A study of Mus musculus with 16 samples.

How the data were processed

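RNA of the NSR and of the isolated RPE from 8 mice was measured on 16 one-colour Affymetrix Mouse Gene 1.0 ST arrays, 1 per tissue and mouse. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit, and cDNA was amplified with the Ovation Pico system and end-labelled with biotin. The authors deposited log2 expression values for 35556 transcript clusters, made with RMA in Partek 6.6 per the submitters' processing notes. That the scale is log2 was read from the values, which lay between 2.20 and 13.84, and the annotation version, probe filters and any centring are not given in the sources used here. The deposited values hold no background or detection measure, so that how far a gene's signal stood above background is unknown. The labels used here name no batch or scan day.

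Groups and replicate numbers came from the labels, which give tissue, treatment and mouse. Among 120 pairs of arrays 0 had identical values, and the smallest mean difference between arrays was 0.178 on the log2 scale. Gene symbols came from the platform annotation: 21789 clusters had 1 symbol, 1621 several and 12146 none here, and 21698 of the first were found by gene identifier in a table of the GRCm38.p6 assembly, with 0 symbols changed. Each gene took its brightest cluster by the mean over all arrays, which left 19938 genes, of which 999 had over 1 cluster. Clusters with several symbols or none were left out of the gene tests.

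The analysis of the deposited values used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Light and control arrays were compared within each tissue with lmFit and eBayes. The difference of the responses and the tissues of control mice were compared in a fit of all 16 arrays with 4 group means. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 48 gene lists, for pathways, cell types and housekeeping genes, each with at least 5 measured genes, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. They were also tested with an estimated correlation and with fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Members adjusted over the list alone were counted from the same p-values. Overlaps were tested with Fisher's exact test.

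The design, the lists, the tests and the alternatives were chosen before the data were examined, apart from those said to be chosen later. The rule for named genes took, for light in each tissue, the 8 largest rises and 8 largest falls among called genes whose light and control arrays did not overlap, leaving out predicted and clone names. To these it added for each list the 2 called genes with the largest change, 4 for the iron, complement, antioxidant, rod and RPE lists. A list without a called gene gave the 2 genes with the largest change, as values only. For the difference of responses and for the tissues it took the 5 largest each way, and for the tissues also the marker lists. It gave 98 genes for the NSR, 100 for the RPE, 10 for the difference and 45 for the tissues, of which 92, 92, 10 and 45 were called. Fewer are printed, and which of them was chosen after their values and a first run of the alternatives had been seen. The printed genes are more stable than the rule's genes as a whole: outside the 2-fold threshold, 83 of the 84 printed values kept their call under all alternatives run, against 214 of the 239 called by the rule. Guca1a, the printed value that lost its call, had been left out and was put back for that reason, as was Kdr because it went against the other endothelial gene.

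The labels give NSR and RPE of 1 mouse the same identifier, so these are paired by animal. Their deviations from the group means correlated between -0.011 and 0.053 over the 8 mice. Fits with the mouse as a block, and with each array left out, other scaling, a filter on the dimmest 25% of genes, other priors, array weights, other handling of clusters and a 2-fold threshold were run as alternatives.

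The fits were tested on simulated values of 19938 genes with known changes. Of genes changed 1.5-fold, 85.5% were recovered for the NSR, 80.5% for the RPE, 54.2% for the difference and 86.8% for the tissues. At 2-fold the shares were 96.4%, 96.4%, 92.2% and 98.7%, and 9, 9, 6 and 12 unchanged genes were called. A list shifted by 0.3 on the log2 scale was called in each of the 3 list comparisons, and 0 other lists were called, in simulated values whose genes varied independently.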

Results

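Gene expression was measured in 2 tissues of 8 male Balb/cJ mice aged 10 weeks, an albino strain. The tissues were the neurosensory retina (NSR), which holds the photoreceptors and the other retinal neurons, and the isolated retinal pigment epithelium (RPE), the cell layer behind the photoreceptors. Of the 8 mice, 4 had received bright fluorescent light of 10000 lux over 18 hours and were killed 4 hours after it ended, and 4 control mice had stayed on a 12-hour cycle. Each of the 16 samples had its own array, so that each of the 4 groups held 4 mice. The values are log2 expression values as deposited, and array medians lay between 6.55 and 6.57 in control NSR, 6.52 and 6.55 in light-exposed NSR, 6.41 and 6.42 in control RPE, and 6.38 and 6.43 in light-exposed RPE. The mean correlation of an array with the others of its group was 0.991 to 0.995. Tissue separated the arrays along the first principal component, which held 84.0% of the variance, and light along the next, with 6.2%. The study asked how photic injury changes expression in each tissue, with iron handling, complement and antioxidant genes of particular interest. The number of arrays limits the precision of every value. Bright light cannot be told apart from the change of light schedule in any of the light comparisons.

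The comparison of control RPE with control NSR asked how the dissected tissues differed. Control RPE held more mRNA of Rpe65 and Lrat, the isomerase and the acyltransferase of the visual cycle, and of Dct, an enzyme of melanin synthesis. Rpe65 stood at 12.90 ± 0.04 in control RPE and 5.10 ± 0.68 in control NSR (SD, n = 4), a 224-fold difference, and Dct and Lrat were 165-fold and 160-fold higher. Neuronal genes were higher in control NSR: Neurod4, a transcription factor of retinal interneurons, by 46.2-fold, Gabrb2, a GABA receptor subunit, by 44.5-fold, and Scg3, a secretory granule protein, by 40.2-fold. The log2 difference of Gabrb2 ranged from -5.48 to -3.53 over its 3 transcript clusters. The rod gene Rp1 was 30.0-fold, the cone arrestin gene Arr3 22.8-fold and the ganglion cell gene Nefm 22.1-fold higher in NSR. Rpe65, Dct, Lrat, Gabrb2, Scg3, Arr3 and Nefm had means below 5.63 in the tissue where they were lower, among the dimmest 25% of genes. The height above background is unknown there, so that the sizes of these folds are uncertain.

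Genes of neighbouring cell types differed between the tissues too. Dcn, a fibroblast proteoglycan, was 37.3-fold higher in control RPE, with a mean of 5.49 in control NSR that lay in the same dim range, and Csf1r, a receptor of macrophages and microglia, 20.7-fold. Endothelial genes went both ways: Ramp2, a receptor partner, was 27.1-fold higher and Kdr, a receptor for VEGF, 5.96-fold lower in control RPE. List medians in control RPE and control NSR were 7.45 ± 0.27 and 6.53 ± 0.04 for fibroblasts and pericytes and 7.11 ± 0.19 and 5.96 ± 0.03 for microglia and macrophages (SD, n = 4). For the endothelium they lay between 6.37 and 6.63 in control RPE and between 6.28 and 6.31 in control NSR. Rod markers were well below their retinal level but present: the median of 25 rod genes was 7.97 ± 0.33 in control RPE, 7.88 ± 0.50 in light-exposed RPE and 11.67 ± 0.04 in control NSR (SD, n = 4). The median of the 26 RPE markers was 11.57 ± 0.04 in control RPE and 6.47 ± 0.10 in control NSR. Single RPE arrays stood apart in markers of other tissues. Lens markers had a median of 7.63 in RPE control 2 against 6.16 to 6.40 in the other RPE control arrays. Corneal and ciliary markers had 7.70 in RPE light 2 against 6.19 to 6.34 in the other light-exposed RPE arrays. Rod markers had 8.58 in RPE light 1 against 7.38 to 7.81 in the other light-exposed RPE arrays. They varied in control RPE too, at 8.32, 8.17, 7.80 and 7.60 in RPE control 1 to 4. In limma, 10961 of 19938 genes differed between the tissues at an adjusted p under 0.05, of which 6140 were higher and 4821 lower in RPE, and 3275 differed at least 2-fold. The share higher in RPE was 56.0%, and 72.2% after centring each array on its median or 66.4% after quantile normalization of all arrays, which moved the median log2 difference of all genes from 0.04 to 0.18 or 0.15.

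**Figure D1:**
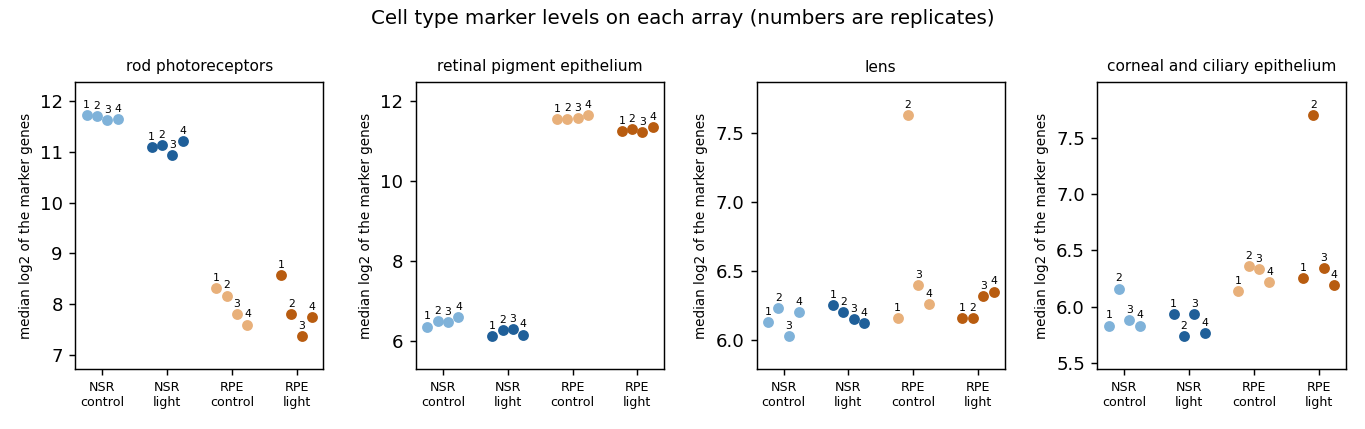
Median log2 value of rod, RPE, lens, and corneal and ciliary marker genes (y axes) on each of the 16 arrays, by group (x axes), with points numbered by replicate. RPE control 2 stands apart in lens markers at 7.63, RPE light 2 in corneal and ciliary markers at 7.70, and RPE light 1 is the highest RPE array in rod markers at 8.58.

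In the NSR, light raised genes of the interferon response, of reactive glia and of chemokine signalling, and lowered genes of rods and cones, as called by camera. With an estimated correlation the call of reactive glia held (adjusted p = 0.029), and those of the interferon response (adjusted p = 0.0559), of chemokines, rods and cones (adjusted p = 0.0875 for each) were lost. Ccl2, a chemokine that attracts monocytes, rose 18.6-fold (log2 4.22, SE 0.20, n = 4 per group, limma adjusted p = 7.56e-08). S100a6, a calcium-binding protein of reactive glia, rose 12.3-fold, the interferon-induced GTPases Irgm1 and Mx2 rose 11.5-fold and 10.2-fold, and the interferon-induced Rtp4 rose 8.25-fold. Opn1sw, the opsin of short-wavelength cones, was 4.57-fold lower (log2 -2.19, SE 0.13, adjusted p = 2.95e-07), and Glb1l3, a galactosidase-like gene, was 5.74-fold lower. For each NSR gene named here, the 4 light-exposed arrays all lay on one side of the 4 control arrays.

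Of 26 interferon response genes, 20 rose and 0 fell over all genes tested, 21 rose when adjusted over the list alone, and the median log2 change was 2.00 (camera adjusted p = 6.63e-26, adjusted p = 0.0559 with an estimated correlation). Reactive glia genes rose as a group, with 21 of 26 higher, 23 adjusted over the list alone, and a median of 1.32 (adjusted p = 1.24e-26, and adjusted p = 0.029 with an estimated correlation). Of 28 genes of the gp130-STAT3 pathway, which carries signals of the LIF and IL-6 cytokines, 15 rose, 16 adjusted over the list alone (adjusted p = 4.31e-15, adjusted p = 0.0559 with an estimated correlation). Of 21 NF-kB target genes 15 rose and 1 fell, 16 and 2 adjusted over the list alone, with a median of 0.49 (adjusted p = 5.6e-09, adjusted p = 0.0728 with an estimated correlation). Serpina3n, an acute-phase protease inhibitor, rose 7.29-fold, and Lif, a cytokine known to protect photoreceptors, rose 5.62-fold. Of 37 chemokines and cytokines, 20 rose, 21 adjusted over the list alone (adjusted p = 1.83e-11, adjusted p = 0.0875 with an estimated correlation). Among 32 immediate early genes 19 rose, 21 adjusted over the list alone (adjusted p = 8.64e-14, adjusted p = 0.0876 with an estimated correlation), with the transcription factors Egr2 up 6.83-fold and Myc up 6.73-fold. Of 30 ribosome biogenesis genes 20 rose, 25 adjusted over the list alone, with Ddx21, a nucleolar helicase, up 1.62-fold (adjusted p = 8.64e-14, adjusted p = 0.1 with an estimated correlation).

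Iron handling genes of the NSR moved both ways: 8 of 41 rose and 3 fell, 10 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.0985), with a median of -0.02 against a mean of 0.26. Hmox1, which releases iron from heme, rose 6.70-fold (log2 2.74, SE 0.15, adjusted p = 1.54e-07), Lcn2, which binds iron carriers, 4.35-fold, and Cp, the ferroxidase ceruloplasmin, 3.87-fold (log2 1.95, SE 0.06, adjusted p = 2.49e-09). Of 35 complement genes 10 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 0.0189, adjusted p = 0.0915 with an estimated correlation). C3ar1, the receptor of the C3a fragment, rose 4.39-fold, Serping1, the C1 inhibitor, 3.97-fold, and Cfi, which cleaves C3b, 2.32-fold. Of 48 antioxidant defence genes 16 rose and 3 fell, 17 and 4 adjusted over the list alone (adjusted p = 0.00123, adjusted p = 0.224 with an estimated correlation). The metallothionein gene Mt2 rose 6.13-fold and Slc7a11, a cystine transporter that feeds glutathione synthesis, 3.60-fold.

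Rod genes fell together in the NSR: 23 of 25 fell and 0 rose, 24 fell adjusted over the list alone, and the median change was -0.52 (adjusted p = 5.09e-23, adjusted p = 0.0875 with an estimated correlation). Reep6, a protein of rod membranes, was 2.45-fold, Fscn2, an actin-bundling protein of photoreceptors, 2.05-fold, and Gucy2f, a guanylate cyclase of the outer segment, 1.79-fold lower. Of 13 cone genes 9 fell and 1 rose, the same counts adjusted over the list alone, with a median of -0.90 (adjusted p = 5.15e-06, adjusted p = 0.0875 with an estimated correlation), and Arr3 was 3.21-fold lower. Bipolar cell genes fell as a group, with 6 of 16 lower and 1 higher, 8 and 3 adjusted over the list alone (adjusted p = 0.0248, adjusted p = 0.224 with an estimated correlation), among them Prkca, a kinase of rod bipolar cells, 1.39-fold lower. Of 18 Müller glia genes 7 rose and 7 fell, 7 and 10 adjusted over the list alone, and the list was not called (adjusted p = 0.355). Rlbp1, the retinaldehyde-binding protein of these cells, was 2.90-fold lower, and Spc25, on this list but known as a kinetochore component, 6.01-fold lower. Of 22 microglia and macrophage genes 6 rose and 0 fell, the same counts adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.266 with an estimated correlation), with Cd68, a lysosomal protein of phagocytes, up 3.48-fold. Of 16 visual cycle genes 2 rose and 6 fell in the NSR, 2 and 8 adjusted over the list alone (adjusted p = 0.00526, adjusted p = 0.0875 with an estimated correlation). Of 24 cytosolic ribosomal protein genes 5 rose and 0 fell, 7 and 0 adjusted over the list alone (adjusted p = 0.00081, adjusted p = 0.224 with an estimated correlation). Of 27 proteasome subunit genes 2 rose and 0 fell, the same counts adjusted over the list alone (adjusted p = 0.00477, adjusted p = 0.286 with an estimated correlation). Of 29 extracellular matrix and remodelling genes 9 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.224 with an estimated correlation).

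In control NSR, Irgm1, Mx2, Myc and Cfi lay below 5.63, so that the sizes of their folds are uncertain. In all, 1769 genes rose and 1244 fell in the NSR, 3013 of 19938, of which 269 changed at least 2-fold, 227 higher and 42 lower. The share that rose was 58.7%, and 67.3% after centring each array on its median (2036 higher, 989 lower) or 59.6% after quantile normalization within the tissue. The light and control arrays did not overlap for 2139 higher and 1987 lower genes, where chance gives 2.86% of genes in both directions together. Camera with its preset correlation called 27 of 48 lists, 19 higher and 8 lower, and 1 of these held with an estimated correlation. Other splits of the 8 mice, which can keep part of the light effect, called up to 18 lists. For 5 of the 48 lists the median and the test differed in sign. The call of RPE markers in the NSR, with 5 of 26 lower and 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.0391, adjusted p = 0.174 with an estimated correlation), was lost without NSR control 3 (adjusted p = 0.0769) or NSR light 3 (0.0986).

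**Figure D2:**
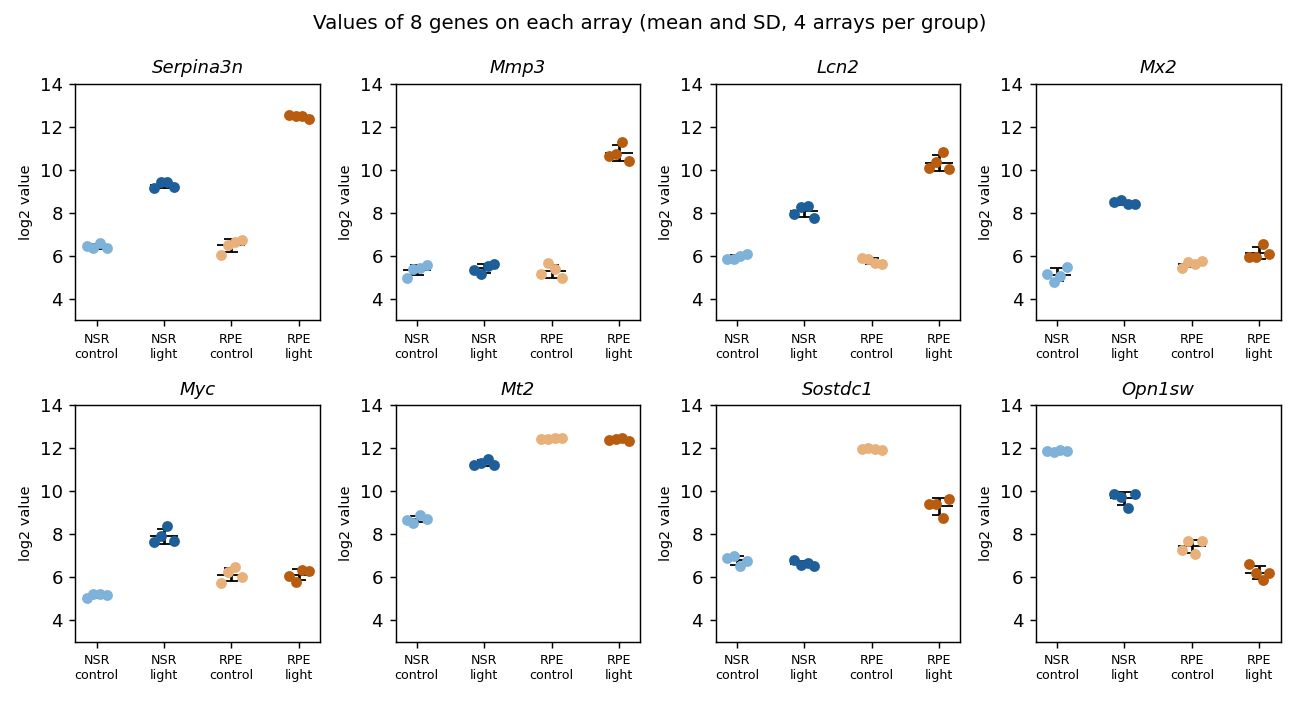
Log2 values (y axes) of 8 genes on each array by group (x axes), with points for single arrays and bars for the mean and SD of 4 arrays. Serpina3n rose 7.29-fold in the NSR and 64.2-fold in the RPE, Mmp3 rose 44.8-fold in the RPE, and Mx2 rose 10.2-fold in the NSR.

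In the RPE, light raised NF-kB target genes and lowered RPE marker, visual cycle and cholesterol synthesis genes, as called by camera. None of these calls held with an estimated correlation (adjusted p = 0.0653 for NF-kB targets, adjusted p = 0.242 for RPE markers, adjusted p = 0.319 for the visual cycle and adjusted p = 0.204 for cholesterol synthesis). Serpina3n rose 64.2-fold (SE 0.13 on the log2 scale, n = 4 per group, limma adjusted p = 1.45e-08). The matrix metalloproteinases Mmp3 and Mmp12 rose 44.8-fold and 24.3-fold, Serpinb1a, an inhibitor of neutrophil proteases, 36.1-fold, and Timp1, an inhibitor of metalloproteinases, 9.87-fold. The extracellular matrix and remodelling list was not called in the RPE (adjusted p = 0.0709), with 8 of 29 genes higher and 3 lower. The counts adjusted over the list alone were the same, and adjusted p = 0.534 with an estimated correlation. It was called higher by fry (adjusted p = 0.00531), with the replicate number as a block (0.0338), without RPE control 2 (0.0164), RPE control 3 (0.0419) or RPE light 1 (0.0317), and without RPE control 2, RPE light 1 and RPE light 2 together (0.00724). Sostdc1, an antagonist of BMP and Wnt signalling, was 6.29-fold lower (log2 -2.65, SE 0.16, adjusted p = 8.85e-06), Lrit2 5.65-fold, Trhde, a peptidase that degrades thyrotropin-releasing hormone, 4.29-fold, and Dapl1 3.88-fold lower. For each RPE gene named here except Guca1a, the 4 light-exposed arrays all lay on one side of the 4 control arrays.

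Of 21 NF-kB target genes 15 rose and 0 fell in the RPE, 16 adjusted over the list alone, with a median of 0.79 (adjusted p = 1.76e-13, adjusted p = 0.0653 with an estimated correlation). Of 26 reactive glia genes 14 rose and 0 fell, 16 and 0 adjusted over the list alone, with a median of 0.82 (adjusted p = 1.76e-13, adjusted p = 0.0865 with an estimated correlation). Of 28 gp130-STAT3 genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone (adjusted p = 1.36e-10, adjusted p = 0.0585 with an estimated correlation). Of 37 chemokines and cytokines 11 rose and 1 fell, 13 and 1 adjusted over the list alone (adjusted p = 0.000115, adjusted p = 0.211 with an estimated correlation), with Il6 up 3.69-fold and Ccl2 3.52-fold. Interferon response genes rose less than in the NSR, with 10 of 26 higher and a median of 0.25, or 13 higher and 1 lower adjusted over the list alone (adjusted p = 5.01e-06, adjusted p = 0.0865 with an estimated correlation). Of 17 neutrophil and monocyte markers 5 rose and 0 fell, 6 and 0 adjusted over the list alone (adjusted p = 0.00128, adjusted p = 0.135 with an estimated correlation). Lcn2, which is on that list and is also made by epithelia under stress, rose 23.7-fold (log2 4.57, SE 0.16, adjusted p = 2.89e-07). Of 22 microglia and macrophage markers 2 rose and 1 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.551). Cd68 rose 6.78-fold while Csf1r was 2.20-fold lower.

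Of 24 cytosolic ribosomal protein genes 17 rose in the RPE, 22 adjusted over the list alone (adjusted p = 1.08e-13, adjusted p = 0.137 with an estimated correlation), with Rps19 up 1.67-fold. Of 30 ribosome biogenesis genes 23 rose and 1 fell, 26 and 1 adjusted over the list alone (adjusted p = 1.76e-13, adjusted p = 0.0653 with an estimated correlation), with the nucleolar gene Nop58 up 2.01-fold. Of 27 proteasome subunit genes 16 rose and 1 fell, 20 and 1 adjusted over the list alone (adjusted p = 1.27e-09, adjusted p = 0.0969 with an estimated correlation), with Psmc4 up 1.52-fold.

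Genes that mark the RPE itself fell: 16 of 26 RPE markers fell and 1 rose, 18 and 1 adjusted over the list alone, with a median of -0.30 (adjusted p = 5.93e-08, adjusted p = 0.242 with an estimated correlation). Slc4a5, a bicarbonate transporter, was 2.25-fold and Tyrp1, a melanosome enzyme, 1.81-fold lower, while Cdh3, the P-cadherin gene, rose 1.70-fold. Of 16 visual cycle genes 10 fell and 1 rose, 11 and 1 adjusted over the list alone (adjusted p = 4.62e-05, adjusted p = 0.319 with an estimated correlation), with the retinol dehydrogenase gene Rdh11 1.88-fold lower. Of 14 melanocyte genes, a list that shares pigment genes with the RPE, 9 fell and 1 rose, 9 and 2 adjusted over the list alone (adjusted p = 0.000148, adjusted p = 0.271 with an estimated correlation). Of 20 cholesterol synthesis genes 14 fell and 0 rose, 16 and 2 adjusted over the list alone (adjusted p = 7.11e-08, adjusted p = 0.204 with an estimated correlation), with Insig1, a sterol sensor, 2.73-fold and Idi1, an enzyme of the pathway, 2.31-fold lower. Bmp2, a growth factor, was 2.02-fold lower. Of 20 circadian clock genes 9 fell and 1 rose, 10 and 2 adjusted over the list alone (adjusted p = 0.00339, adjusted p = 0.319 with an estimated correlation). The clock repressor gene Ciart was 1.72-fold lower by its brightest transcript cluster, with a log2 change of -0.30 at the other, and the control mice had been kept on another light schedule.

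Iron handling genes of the RPE again moved both ways, with 5 of 41 higher and 7 lower, the same counts adjusted over the list alone (adjusted p = 0.992), and a median of -0.03 against a mean of 0.15. Hmox1 rose 4.84-fold (log2 2.28, SE 0.16, adjusted p = 2.4e-05) and Tfrc, the transferrin receptor gene, 2.45-fold (log2 1.29, SE 0.08, adjusted p = 8.96e-06). Of 35 complement genes 3 rose and 1 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.363), with C4b up 2.41-fold and Cfi 2.37-fold. Of 48 antioxidant defence genes 10 rose and 9 fell, 11 and 9 adjusted over the list alone, and the list was not called (adjusted p = 0.415). Gsta3, a glutathione transferase, rose 9.88-fold and Gclc, the catalytic subunit of glutathione synthesis, 1.89-fold, while Nqo1, a quinone reductase, was 3.76-fold lower.

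Of 25 rod genes 4 fell and 0 rose in the RPE samples, the same counts adjusted over the list alone (adjusted p = 0.003, adjusted p = 0.657 with an estimated correlation, and not called by fry, adjusted p = 0.159), with Gucy2f 2.05-fold lower. Guca1a was 2.83-fold lower (log2 -1.50, SE 0.41, adjusted p = 0.0306). Its call was lost without any single RPE array except RPE light 1, with adjusted p = 0.0792, 0.0789, 0.0537 and 0.0514 without RPE control 1 to 4 and 0.0615, 0.056 and 0.0749 without RPE light 2 to 4. Of 13 cone genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone (adjusted p = 0.0044, adjusted p = 0.204 with an estimated correlation). The lists of bipolar cells (adjusted p = 0.157), amacrine and horizontal cells (0.216), ganglion cells (0.563) and Müller glia (0.956) were not called with all 8 RPE arrays. The bipolar list was called lower without RPE light 1 (adjusted p = 0.00244), the array with the most rod transcripts, and without RPE control 2, RPE light 1 and RPE light 2 together (0.000443). The amacrine and horizontal list was called lower without those 3 arrays (adjusted p = 0.0404) and by fry (0.00409). Each of these choices of arrays kept RPE control 1, with a rod marker median of 8.32. An unequal amount of retina in the samples was thus not told apart from an effect of light on these lists. The lower lens list, with 1 of 19 genes lower, over all genes and adjusted over the list alone (adjusted p = 0.0234, adjusted p = 0.698 with an estimated correlation), was lost without RPE control 2 (adjusted p = 0.59) or RPE light 3 (0.0636).

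In control RPE, Mmp3, Cfi and Il6 lay below 5.63, so that the sizes of their folds are uncertain. In all, 1810 genes rose and 1700 fell in the RPE, 3510 of 19938, of which 295 changed at least 2-fold, 152 higher and 143 lower. The share that rose was 51.6%, and 54.6% after centring each array on its median. The light and control arrays did not overlap for 2247 higher and 2165 lower genes, against 2.86% of genes by chance. Without RPE control 2, RPE light 1 and RPE light 2, a choice made after seeing the data, 2056 genes changed, of which 1886 were called in the same direction with all 8 arrays. Camera called 19 of 48 lists, 10 higher and 9 lower, and 0 with an estimated correlation, where 11 lists had an unadjusted p under 0.05, while fry called 29. Of the 35 splits of the mice, 8 called as many lists as the real one or more, up to 23. Other splits can keep part of the light effect, so that their counts are not those of chance alone. The number of lists in the RPE did not exclude chance. The median and the test differed in sign for 4 of the 48 lists.

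**Figure D3:**
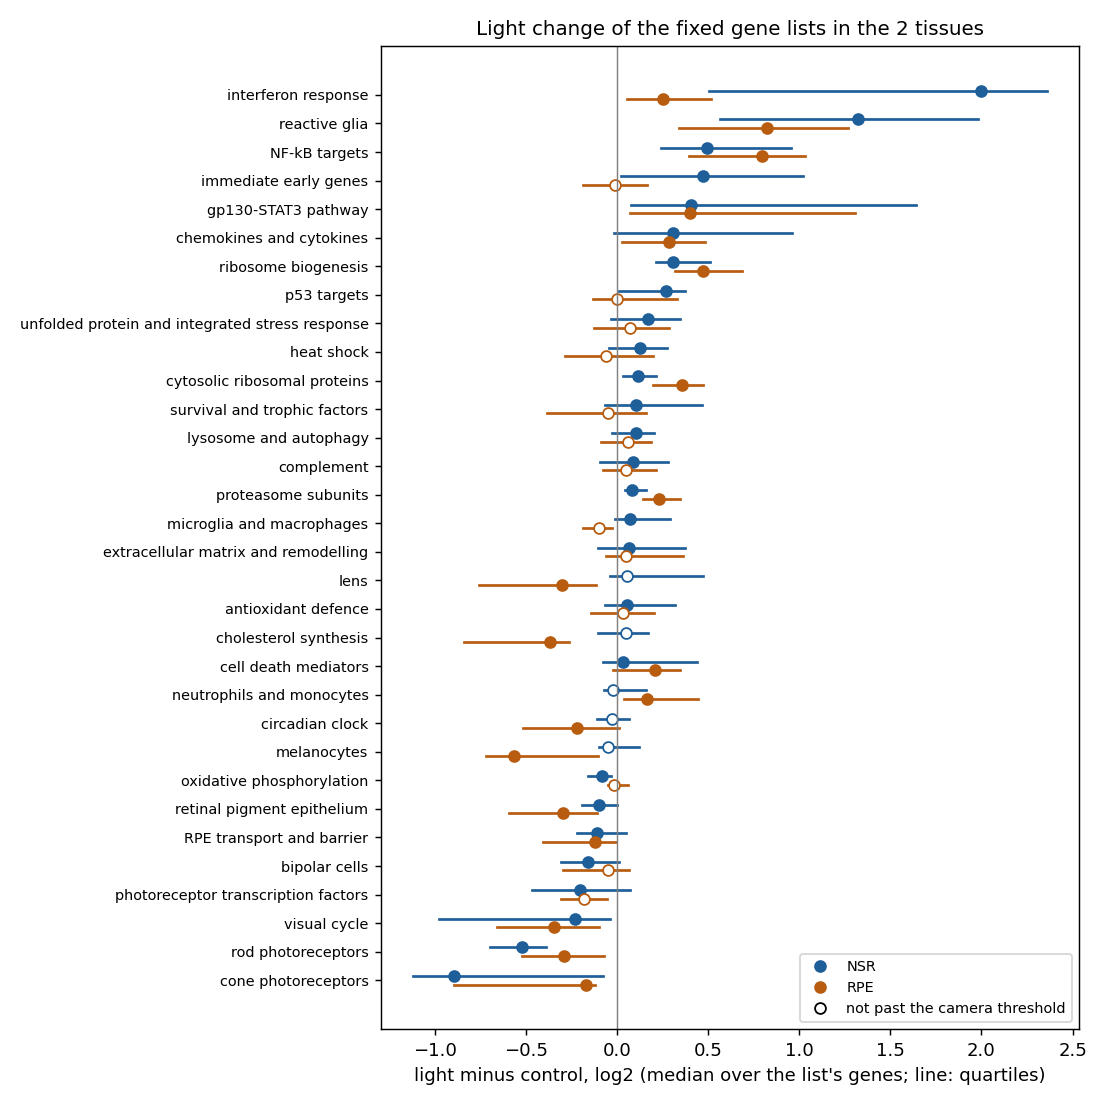
Median log2 change with light (x axis) of each gene list called in at least 1 tissue (y axis), in the NSR and the RPE, with lines for the quartiles over the genes and open circles where camera did not call the list. Interferon response genes have a median of 2.00 in the NSR and 0.25 in the RPE, and rod genes -0.52 in the NSR and -0.29 in the RPE.

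The difference between the responses, RPE minus NSR, asked which genes light changed unequally in the tissues. The largest differences above 0 were those of Mmp3 (log2 5.42, SE 0.25), Serpinb1a (5.20, SE 0.22), Mmp12 (3.96, SE 0.32), Gsta3 (3.38, SE 0.21) and Serpina3n (3.14, SE 0.16), with limma adjusted p between 2.22e-10 and 2.79e-07. The NSR response was the larger for Mx2 (-2.82, SE 0.20), Myc (-2.76, SE 0.23), Ddx58, a sensor of viral RNA (-2.72, SE 0.16), and Mt2 (-2.67, SE 0.11), with adjusted p between 2.22e-10 and 4.5e-07. Interferon response genes stood out as a group: 18 of 26 responded less in the RPE and 0 more, 19 and 0 adjusted over the list alone, with a median difference of -1.17 (adjusted p = 6.24e-19, and adjusted p = 0.0181 with an estimated correlation). Survival and trophic factor genes responded less in the RPE too, with 11 of 26 lower and 0 higher, 13 and 0 adjusted over the list alone (adjusted p = 8.95e-06, and adjusted p = 0.0288 with an estimated correlation).

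Immediate early genes responded less in the RPE, with 15 of 32 lower and 1 higher, 17 and 2 adjusted over the list alone (adjusted p = 6.11e-07, adjusted p = 0.362 with an estimated correlation). Their list median was already higher in control RPE, at 7.78 ± 0.25 against 6.92 ± 0.08 in control NSR (SD, n = 4). After light it was 7.91 ± 0.09 in the RPE and 7.59 ± 0.09 in the NSR. A weaker response was not told apart from a higher starting level. Of 20 cholesterol synthesis genes 13 were lower and 0 higher, 16 and 0 adjusted over the list alone (adjusted p = 5.28e-11, adjusted p = 0.0578 with an estimated correlation). Of 24 ribosomal protein genes 7 responded more in the RPE and 0 less, 10 and 1 adjusted over the list alone (adjusted p = 6e-05, adjusted p = 0.362 with an estimated correlation). The antioxidant list had 10 of 48 genes lower and 5 higher, the same counts adjusted over the list alone (adjusted p = 0.0324, adjusted p = 0.414 with an estimated correlation), and this call was lost without control mouse 1 (adjusted p = 0.0576) or light mouse 3 (0.0833). NF-kB targets responded more in the RPE, with 5 of 21 higher and 1 lower, 7 and 1 adjusted over the list alone (adjusted p = 0.0166, adjusted p = 0.393 with an estimated correlation). This call was lost without control mouse 1 (adjusted p = 0.0525). For reactive glia the difference was not called (adjusted p = 0.0832). The response of that list was called less in the RPE without light mouse 2 (adjusted p = 0.0225) or the 3 RPE arrays with transcripts of other tissues (0.0148). Differences in the iron (adjusted p = 0.241) and complement (adjusted p = 0.451) lists did not pass the test. In all, 1029 genes responded more positively and 1606 less so in the RPE, 2635 of 19938, of which 433 differed at least 2-fold, 110 more positively and 323 less so. Camera called 18 of 48 lists, 2 of them with an estimated correlation. Other splits of the mice, which can keep part of the light effect, called up to 16. Median and test differed in sign for 7 lists.

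The responses of the tissues also overlapped. Of the genes called in each tissue, 644 rose in both, against 160.6 for independent lists (Fisher's exact test, two-sided, p = 2.01e-253), and 290 fell in both, against 106.1 (p = 5.57e-61). Hmox1, Lcn2, Serpina3n, Ccl2, Cfi and Cd68 were among the genes that rose in both. By the same exact test, 55 genes fell in the NSR and rose in the RPE, fewer than the 112.9 of independent lists (p = 1.46e-10), and 131 rose in the NSR and fell in the RPE, against 150.8 (p = 0.0819). Genes are not independent replicates, so that the p-values of these exact tests do not measure the spread between mice. The expected numbers also count the dimmest 25% of genes, of which only 3.4% were called in the NSR and 2.5% in the RPE, and this lowers them. Across genes, the log2 changes of the tissues had a Pearson correlation of 0.331 and a Spearman correlation of 0.265. The tissues came from the same mice, so that differences between mice were part of both lists. The RPE samples also held rod transcripts, with a list median of 7.97 in control RPE and 7.88 in light-exposed RPE. Retina in the RPE samples could thus add to the overlap, and it was not told apart from a response of both tissues. Of the 1893 genes called in the NSR alone, 747 also passed the test of the difference, as did 1221 of the 2390 called in the RPE alone.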

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

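The tests of the interferon pattern, with the condition that markers be brighter than the median gene to exclude a cell type, and leaving out 3 RPE arrays together, also in the test of RPE markers, were chosen only after the result was seen, as was the bootstrap interval asked of ratios of SD to SE; the ratio of SD to SE of RPE markers and the other splits of the mice were chosen before their values were seen.

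Interferon response genes rose in the NSR and far less in the RPE, with a median difference of -1.17 (camera adjusted p = 6.24e-19, and adjusted p = 0.0181 with an estimated correlation). A high starting level that left little room to rise stays open: over the 23 members higher in control RPE than in control NSR, light-exposed RPE minus light-exposed NSR had a median of -0.065, near 0 over members that went both ways, and 9 of the 23 rose in the RPE, while the 3 members not higher there, with a median response difference of -1.892 (bootstrap interval -2.171 to -0.050), are too few, and the list median, at 6.99 to 7.22 on the light-exposed RPE arrays and 7.84 to 8.25 on those of the NSR, goes against it without deciding it, since it is the level of the middle members and the differences of single members went both ways. This was the fourth form of the test: the first, the median control difference of all 26 members (0.335), would have argued against a high starting level, the second, their median difference after light (-0.086), would have favoured it, and the third (-1.377) was dropped because its 12 members had been chosen for a smaller response in the RPE, which largely fixed its outcome. Lymphocytes, neutrophils or monocytes entering the retina stay open too. Their markers showed no broad rise, with a median change of -0.041 (quartiles -0.08 to 0.02, 1 of 29 rose). They were dim at a median of 5.09 in light-exposed NSR, against 6.76 for all genes. A small number of such cells might not show in dim markers, so that the test does not decide it. More microglia or macrophages also stay open. Their markers had a median change of 0.069 at a median level of 6.07, with 6 of 22 higher and 0 lower. The list was called higher (camera adjusted p = 0.0152, adjusted p = 0.266 with an estimated correlation). Without the condition on brightness, both -0.041 and 0.069 would have argued against more of these cells. A difference in how the cells of each tissue respond stays open as well, since it was not tested apart from these explanations.

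RPE markers were lower in light-exposed RPE, with a median of -0.30 (camera adjusted p = 5.93e-08, adjusted p = 0.242 with an estimated correlation). A smaller share of RPE cells would lower markers made by RPE cells alone by like amounts. Over 16 markers at least 16-fold higher in control RPE than in control NSR, the changes ran from -1.17 for Slc4a5 to 0.76 for Cdh3. Their SD was 5.72 times their median SE (bootstrap interval 3.25 to 7.47). This choice does not set RPE cells apart from other cells in the RPE samples, and Dct among them is also a melanocyte gene. The ratio argues against a smaller share as the whole cause only if RPE cells alone made these markers. That was not tested. The 3 RPE arrays with lens, corneal or retinal transcripts are argued against as the cause by the median change without them, -0.321. The list was still called lower there (camera adjusted p = 6.16e-07, adjusted p = 0.332 with an estimated correlation). With these fewer arrays 9 of 26 markers were lower and 1 higher. A smaller share of RPE cells stays open, and so does an effect of light on these genes.

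The 8 mice can be split into groups of 4 in 35 ways, and the 8 control arrays likewise. For the NSR, 1 split, the real one, gave as many as its 3013 genes, with 0 genes in the highest other. The same held for the 3510 genes in the RPE (1 of 35, highest other 0), the 2635 whose response differed (1 of 35, highest other 0) and the 10961 between tissues (1 of 35, highest other 0, also over the 8 splits that part all pairs of 1 mouse). For each of these counts the real split ranked first, which is the most that 35 splits can show. The other splits mix light and control arrays, or tissues, within a group, which widens the spread there and makes calls unlikely. The 0 genes of the other splits are thus not what chance alone gives. Only the rank of 1 in 35 argues against chance, and it does not exclude it. For the 27 lists in the NSR the real split ranked first too (1 of 35, highest other 18), and 1 of these calls held with an estimated correlation. For the 18 lists for the difference, 1 of 35 splits called as many and the highest other called 16. This narrow lead does not exclude chance: the real split called 15 lists without control mouse 2 and 16 without light mouse 1. With an estimated correlation 2 of the 18 calls held. For the 19 lists in the RPE chance cannot be excluded either, since 8 of 35 splits called as many or more, and the highest other called 23. Other splits can part the light mice unequally and so keep part of the light effect. Their list counts are therefore not what chance alone gives.

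An array far from the 3 others of its group was found in 27 of 358 groups of values tested, where chance gives about 1 in 20. In NSR light 4 the list medians lay apart at 7.461 for immediate early genes, 6.810 for extracellular matrix, 6.241 for endothelium and 6.392 for erythroid cells. In NSR light 2 the Schwann cell and myelin median was 6.533. In NSR control 4 the fibroblast median was 6.584, and in NSR control 2 the corneal and ciliary median was 6.164. In RPE control 4 the medians were 9.443 for the unfolded protein response, 10.087 for RPE transport and 6.057 for amacrine and horizontal cells. RPE control 2 had a lens median of 7.627 and RPE light 1 a bipolar cell median of 7.402. RPE light 2 had a corneal and ciliary median of 7.697, and RPE light 4 a Schwann cell and myelin median of 7.185. Among genes, NSR light 3 lay apart in Opn1sw at 9.209, Glb1l3 at 6.260, Cp at 11.490 and Lif at 8.585. RPE light 3 lay apart in Hmox1 at 10.646 and Csf1r at 8.689. RPE control 1 lay apart in Cd68 at 7.483, Idi1 at 9.083 and Ramp2 at 10.616. RPE control 2 had Gclc at 8.573 and RPE control 3 had Tyrp1 at 12.342. NSR control 1 had Csf1r at 6.041 and Ddx58 at 6.190.

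The light response differed between the tissues for 2635 genes. Of the genes named for a light response, 49 of 56 were among them, given here as RPE minus NSR on the log2 scale. The response was less in the RPE for Ccl2 (-2.404), Mx2 (-2.824), Irgm1 (-2.417), Rtp4 (-2.211), S100a6 (-2.358), Cp (-1.166), C3ar1 (-1.937), Serping1 (-1.625), Mt2 (-2.665) and Slc7a11 (-1.498). It was also less for Lif (-1.953), Egr2 (-2.448), Myc (-2.759) and Ddx58 (-2.716). Genes that were lowered more, or raised less, in the RPE were Sostdc1 (-2.508), Lrit2 (-1.865), Trhde (-1.775), Dapl1 (-0.959), Nqo1 (-1.910), Bmp2 (-1.414), Insig1 (-1.371) and Idi1 (-1.095). To these came Rdh11 (-0.799), Slc4a5 (-0.980), Tyrp1 (-0.980) and Csf1r (-1.170). Genes that were lowered more in the NSR were Spc25 (2.196), Opn1sw (0.980), Glb1l3 (2.603), Arr3 (1.529), Rlbp1 (0.819), Reep6 (1.078) and Fscn2 (0.899). Arr3 lay below 5.63 in control RPE, in the dim range, where a fall may not show. The response was greater in the RPE for Lcn2 (2.448), Serpina3n (3.138), Cd68 (0.960), Mmp3 (5.418), Serpinb1a (5.197), Mmp12 (3.962), Gsta3 (3.379) and Timp1 (1.717). It was also greater for Tfrc (1.608), C4b (1.076), Gclc (0.664), Il6 (1.607), Cdh3 (0.882), Nop58 (0.464), Rps19 (0.514) and Psmc4 (0.430).

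Among lists, the median difference was -1.173 for interferon response (adjusted p = 0.0181 with an estimated correlation) and -0.369 for survival and trophic factors (0.0288), the 2 calls that held with it. The calls of all other lists named here were lost with an estimated correlation, whose adjusted p follows each median. The median difference was -0.595 for cholesterol synthesis (adjusted p = 0.0578 with an estimated correlation), -0.590 for melanocytes (adjusted p = 0.138), -0.518 for lens (adjusted p = 0.571), -0.515 for immediate early genes (adjusted p = 0.362), -0.204 for heat shock (adjusted p = 0.362) and -0.202 for circadian clock (adjusted p = 0.362). It was -0.104 for outer segment phagocytosis (adjusted p = 0.249 with an estimated correlation), -0.092 for antioxidant defence (adjusted p = 0.414) and -0.073 for chemokines and cytokines (adjusted p = 0.451). It was 0.238 for rods (adjusted p = 0.61 with an estimated correlation), 0.228 for cones (adjusted p = 0.399), 0.209 for NF-kB targets (adjusted p = 0.393) and 0.195 for ribosomal proteins (adjusted p = 0.362). For proteasome subunits it was 0.168 (adjusted p = 0.393 with an estimated correlation), for neutrophils and monocytes 0.166 (adjusted p = 0.0838) and for oxidative phosphorylation 0.097 (adjusted p = 0.539). The differences of the lens and rod lists were not called by fry either (adjusted p = 0.114 and 0.204). Of the 13767 transcript clusters with several symbols or none, which the gene tests left out, light changed 291 in the NSR, 136 higher and 155 lower, and 495 in the RPE, 306 higher and 189 lower.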

How the results depend on the processing

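Leaving out 3 RPE arrays together, or genes at least 4-fold higher in the other tissue, was chosen only after the result was seen, and all other alternatives were chosen before. Leaving out 1 array or mouse gave 2367 to 2920 genes in the NSR, 2913 to 3232 in the RPE, 2105 to 2470 for the difference and 10020 to 11091 for the tissues, and 26 to 28, 18 to 22 and 15 to 19 lists. A 2-fold threshold left 269, 295, 433 and 3275 genes, and 51 genes higher and 3 lower in both tissues, by its construction. Testing all transcript clusters gave 17586 differences between tissues, since more were tested. Without RPE control 2, RPE light 1 and RPE light 2, 2056 genes changed in the RPE, with fewer arrays. An estimated correlation left 1 list in the NSR, 0 in the RPE (11 at an unadjusted p under 0.05) and 2 for the difference, and fry called 29 lists in the RPE; the cause was not tested. Under fry the corneal and ciliary list in the NSR, with a median of -0.082, turned from lower (camera, not called) to higher (adjusted p = 0.00286).

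Of 84 printed gene values 73 kept their call under every alternative run, 10 lost it at the 2-fold threshold alone, and Guca1a lost it under 9 others. Of the genes named by the rule, 25 of 239 lost it under an alternative other than that threshold and 0 reversed. Of 64 list calls 3 held throughout and 51 under all but the estimated correlation. Single mice ended the calls of the NSR heat shock list (control 1, adjusted p = 0.0568; light 4, 0.0577) and, for the difference, of NF-kB targets (control 1, 0.0525), chemokines (control 2, 0.0626; light 2, 0.0676), oxidative phosphorylation (control 2, 0.0636; control 3, 0.0804; light 1, 0.083), cones (control 2, 0.0626; control 3, 0.0992; light 1, 0.0996) and rods (light 1, 0.326). Without the dimmest 25% of genes, 6 calls were lost, those of heat shock (0.054), cell death mediators (0.0893) and survival factors (0.0531) in the NSR and, for the difference, of antioxidant defence (0.0673), NF-kB targets (0.0526) and cones (0.0542). Without the 3 RPE arrays 5 were lost, those of lens in the RPE (0.559) and, for the difference, of oxidative phosphorylation (0.123), rods (0.51), cones (0.0959) and chemokines (0.202), whose median turned from -0.073 to 0.018. Fry ended 4 calls, of rods and lens in the RPE (0.159 and 0.239) and for the difference (0.204 and 0.114). Lists not called became called in 29 cases under fry, 17 without 1 array or mouse, 7 without the 3 arrays and 3 with the replicate block.

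Light and control arrays of 1 number are different animals and correlated at most 0.066, although 4 NSR and 1 RPE arrays matched their own number best. The number as a block gave 2728 genes in the NSR and 2984 in the RPE. With the mouse as a fixed or random block the difference had 2284 or 2647 genes and the tissues 10765 or 10981, and the block gave 28, 21 and 18 lists. It changed no call of a printed gene or of a called list. Among the dimmest 25% of genes, below 5.63, 3.4% were called in the NSR and 2.5% in the RPE, against 19.0% and 22.6% above it, and signal over background is unknown.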

Other observations

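The gene families below were grouped by the stem of the gene symbol and chosen for description only after the result was seen, and the bootstrap interval asked of the paralog test was added after its ratio was seen, and the test of unspliced RNA apart from genomic DNA after the olfactory receptor values were seen; the other tests of the protocadherin genes were chosen before their results were.

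Guanylate-binding proteins, GTPases induced by interferon, rose throughout in the NSR, 8 of 8 with a median log2 change of 1.41 (camera adjusted p = 3.81e-10 over 313 families, adjusted p = 0.52 with an estimated correlation). Poly(ADP-ribose) polymerase genes rose in 8 of 11 cases (adjusted p = 3.81e-07, adjusted p = 0.196 with an estimated correlation), and annexin genes, which code for calcium-dependent membrane-binding proteins, in 7 of 12 (adjusted p = 0.00226, adjusted p = 0.613 with an estimated correlation). Collagen genes fell, with 9 of 44 lower and 0 higher (adjusted p = 0.000317, adjusted p = 0.743 with an estimated correlation). In the RPE, 23 of 49 genes with the stem Eif, used for translation initiation factors among others, rose and 2 fell (adjusted p = 1.22e-07, adjusted p = 0.498 with an estimated correlation). Of 10 Utp genes of the small ribosomal subunit processome 9 rose (adjusted p = 4.85e-07, adjusted p = 0.498 with an estimated correlation), as did 7 of 9 Cct genes, which code for subunits of a chaperonin (adjusted p = 0.00178, adjusted p = 0.595 with an estimated correlation). Nuclear pore genes rose in 10 of 20 cases (adjusted p = 1.2e-05, adjusted p = 0.498 with an estimated correlation) and mitochondrial ribosomal Mrpl genes in 16 of 48 with 1 lower (adjusted p = 3.34e-05, adjusted p = 0.498 with an estimated correlation). Genes with the stem Bmp, used for bone morphogenetic proteins among others, fell in the RPE, with 5 of 12 lower and 1 higher (adjusted p = 0.0343, adjusted p = 0.498 with an estimated correlation). All families named here are symbol stems, which can also hold genes of other functions.

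Protocadherin beta genes, a cluster of neuronal adhesion genes, rose in the NSR: 14 of 22 were higher, with a median log2 change of 0.385 (camera adjusted p = 7.5e-07, adjusted p = 0.196 with an estimated correlation), while in the RPE 0 rose and 2 fell in limma, with a median of -0.172. Genomic DNA is argued against by olfactory receptor genes, also of single coding exons, whose median change was -0.029 over 1015 genes (1 rose, 13 fell) at a median level of 4.34 in control NSR, against 6.98 for the protocadherin genes, since it would add to all genes and raise dim ones most, and a shift of all genes of the same brightness by 0 of 10000 random lists matched on mean value having a median as high (95th percentile 0.048). Unspliced RNA, which the olfactory receptor test had been meant to cover too, stays open, because genes at 4.29 in light-exposed NSR may hardly be transcribed there and could not show it. That 1 transcript was read by the probes of all paralogs may still hold: the SD of the changes was 2.16 times their median SE, beyond the bound of 2 set before, but its bootstrap interval of 1.41 to 2.80 spans that bound, so this and a rise of several genes cannot be told apart. A response of the gene cluster to light in the NSR is a hypothesis found and tested on the same data.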
